A study of Mus musculus with 3 samples.

How the data were processed

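Single cells of newborn mice were profiled with 10x Genomics libraries. The animals were ICR mice at postnatal day 2 that carried HCN4-H2BGFP, in which a nuclear green fluorescent protein is made from the gene of the pacemaker channel HCN4. There were 3 libraries, 1 per group. The cells of the GFP-positive and GFP-negative libraries came from the sinoatrial node region and were sorted by flow cytometry on GFP, and the cells of the RA library were not sorted. The labels name the last library RA and also give its tissue as sinoatrial node region, and this disagreement could not be settled from the counts, so the library is called RA here. Each library was taken as 1 sample, and the number of animals behind it was not stated in the labels.

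The authors deposited raw UMI counts per gene and barcode, and every stored value was a whole number. Cell Ranger and the build mm9 were used per the submitters' processing notes, which gave no version of Cell Ranger. Each matrix held 28001 features, of which 27998 were Ensembl gene IDs and 3 were added reporter features named GFP, hcn4-h2bG-3 and hcn4-h2bG-10. A GENCODE mouse gene table held 27645 of the IDs (98.7%). Its build differed from mm9, so no coordinates are given. In 56 cases several IDs shared a symbol, and those features were kept apart by ID. Among the genes of the fixed lists and marker sets, 2 (Ccl21a and Hbb-b1) were not found under 1 ID and were left out of their sets.

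The 3 libraries held 3346, 3276 and 1450 barcodes, in the order GFP-positive, GFP-negative and RA. Barcodes with at least 500 genes and at most 50% mitochondrial UMIs were kept. Too few genes removed 46, 240 and 153 barcodes, and mitochondrial UMIs removed 11, 4 and 8. Scrublet, as built into scanpy, then marked 7, 7 and 6 cells, which is 20 of 7610 cells (0.263%). That share is far below the usual rate for libraries of this size, so the doublet caller has not worked, and doublets stay among the cells. The cells analysed numbered 3282, 3025 and 1283, with median depths of 12387.5, 11402 and 14136 UMIs. Haemoglobin transcripts made up 0.0915%, 8.89% and 12.4% of the UMIs.

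Counts were scaled per cell and log-transformed, 2000 variable genes were chosen with the members of the fixed lists kept out, and 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0 gave 33 clusters over all libraries together. A cluster took the name of the marker set with the highest mean log2 fold over the median level of the clusters. A marker counted if at least 20% of the cluster's cells had it at a fold of at least 2. A name needed at least 3 such markers, at least 1 own marker among the 10 leading genes and no more from any other set. There were 16 marker sets with 117 markers, and the vascular, endocardial and lymphatic endothelial sets were joined into 1 endothelial set for naming. Classes are called by the name of their set with "-like". Cardiomyocyte-like and endothelial-like cells were clustered again by the same steps.

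UMIs were summed over the cells of a class in a library and given as counts-per-million values of that class (CPM). With 1 library per group there was no replicate error and no test between groups, so no p-value and no count of changed genes is given. Intervals are 95% exact Poisson intervals for CPM, exact conditional binomial intervals for ratios and exact Clopper-Pearson intervals for shares. They cover counting error only. The log2 ratios used 0.5 UMIs added to each sum. Where a class of a library had 0 UMIs of a gene, the fold is a lower bound, written as at least that many fold. It sets the measured level of the other library against a floor of 3 UMIs per summed class. Counting error in that measured level is not included, so with few UMIs the true ratio could lie under the bound. A class of a library needed at least 50 cells to be compared.

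There were 13 gene lists with 142 genes, fixed before the data were examined along with the marker sets, the filters and the comparisons. They cover pacemaker, working atrial, His bundle, ventricular, calcium handling, oxidative metabolism, cell cycle, dissociation stress, extracellular matrix, endothelial progenitor, arterial endothelial, capillary endothelial and venous endothelial genes. A member with at least 10 UMIs in both libraries together was measured. It was called higher or lower when its log2 ratio passed 0.58, about 1.5 times, and its interval left out equality. The others were called between. The median log2 ratio of a list is given with its percentile among 10000 random lists matched on level, only as a description of these libraries. A member is said to be higher in another class where its level in the class compared, pooled over the libraries, was under 0.5 times that elsewhere, since free RNA could then carry it. Genes outside the lists were named by 1 rule. They were the 10 highest and 10 lowest log2 ratios among genes at 50 CPM or more in either library and in at least 10% of the cells of the higher library, with an interval that left out equality, and with a level not under 0.5 times that of another class. Mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of this choice. Some genes of the lists and of this choice are not reported here by name.

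Free RNA was visible. Cluster 10 of the GFP-positive library held cells with airway secretory genes, and Scgb3a1, at 102985 CPM in the unnamed cells of that library, was also read at 319 CPM in its cardiomyocyte-like, 307 CPM in its endothelial-like and 333 CPM in its epicardial-like cells. Scgb3a1, Scgb3a2 and Scgb1a1 were therefore not taken as genes of those classes. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs without replacement, which left out 0 cells. Shares of the classes, shares of the sub-clusters and counts of gene pairs came from separate random draws, so they can differ by a few cells.

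Alternatives planned before the data were examined were no filter, at least 1000 genes with at most 20% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, list genes allowed among the variable genes, classes from each cell's own marker UMIs, 5 UMIs added to each sum, scaling without the 50 most abundant genes, median-of-ratios scaling, and thinning to 1000 or 4000 UMIs. Alternatives added after the data were seen were doublets removed by rank of score at 0.8% per 1000 cells, only the larger cardiomyocyte-like cluster, lists without members higher in another class, and sub-clusters at other resolutions.

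The comparison was tested on simulated data, drawn from 1 profile with known folds. Of genes set to 2-fold, 97.0% were called in simulated cardiomyocyte-like sums and 100% in endothelial-like and fibroblast-like sums. At 1.5-fold these shares were 49.3%, 56.7% and 62.7%, so a difference near 1.5-fold was often missed. Among unchanged genes 0.293%, 0% and 0% were called, and 95.5%, 96.3% and 95.2% of the intervals held the true ratio. The simulated sums held counting error only and no variation between cells. These rates therefore check the computation and need not hold for the real sums. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.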

Results

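Cells were compared between 3 single-cell RNA libraries from HCN4-H2BGFP mice at postnatal day 2. Each group had 1 library and therefore no replicates. The GFP-positive library held cells of the sinoatrial node region sorted for the reporter, and it had 50416748 UMIs in 3346 barcodes. The GFP-negative library held cells of the same region sorted against the reporter, with 38204709 UMIs in 3276 barcodes. The RA library was not sorted and had 19975326 UMIs in 1450 barcodes. All levels are counts-per-million values (CPM), taken over all UMIs of a cell class in 1 library, and ratios are higher or lower levels between single libraries.

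The first comparison asked which kinds of cells each library held. Endothelial-like cells made up 76.5% (95% interval 75.0% to 77.9%) of the GFP-positive library, 6.78% of the GFP-negative library and 21.0% of the RA library. Epicardial-like cells, named from mesothelial markers such as Upk3b, Msln and Krt19, made up 15.8% (14.5% to 17.04%) of the GFP-positive library, 0.694% of the GFP-negative library and 0.156% of the RA library. Cardiomyocyte-like cells were 5.12% (4.39% to 5.93%), 2.08% (1.60% to 2.66%) and 5.53% (4.35% to 6.93%) in the same order, which is 168, 63 and 71 cells. When only the larger cardiomyocyte-like cluster was counted, the GFP-negative and RA shares were 1.29% and 2.96%. The GFP-positive library also held 28 cells with airway secretory genes (cluster 10), so not all of its cells need be of the heart. Whether its epicardial-like and endothelial-like cells all came from the heart was not tested.

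Fibroblast-like cells were 54.4% of the GFP-negative library and 53.4% of the RA library, and 0.366% of the GFP-positive library. Smooth muscle-like or pericyte-like cells were 17.5% of the GFP-negative library against 2.96% in RA and 0.183% in the GFP-positive library. Cluster 28, named fibroblast-like, held 290 RA and 187 GFP-negative cells. Its leading genes included Rgs5 and Tagln of the smooth muscle or pericyte set, so the line between these classes is not sharp. Glial-like cells were 2.71% of the GFP-negative library. None was found in the other two, where the exact interval allows a share of up to 0.112% in the GFP-positive and 0.287% in the RA library. Macrophage-like cells were 0.823%, 3.83% and 8.50%, other leukocyte-like cells 0.0914%, 4% and 1.95%, and erythroid-like cells 0.0305%, 3.40% and 6.39%. Unnamed cells were 1.13%, 4.66% and 0.156%. Shares in the sorted libraries follow the gate and are not shares of the tissue.

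**Figure D1:**
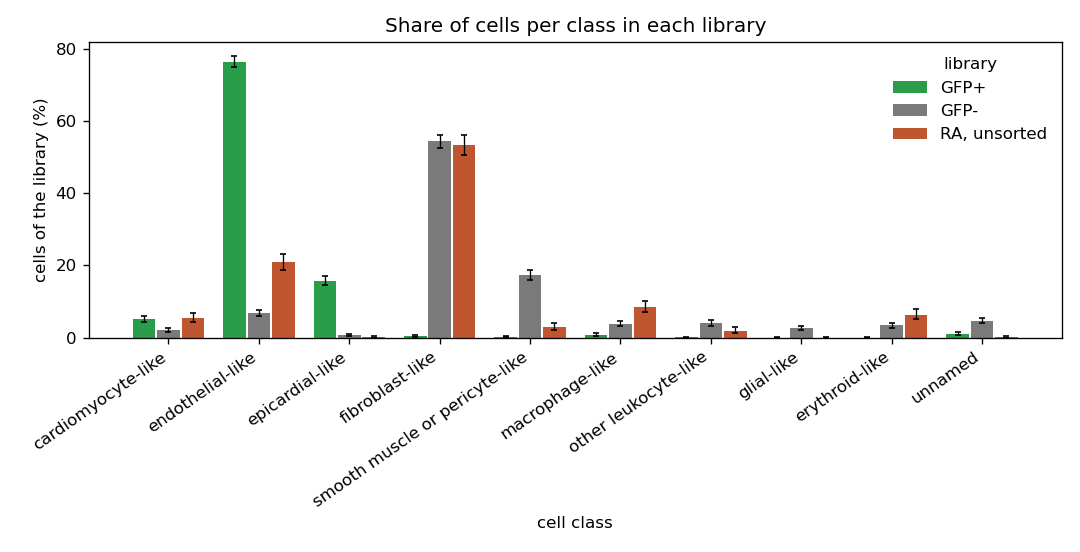
Bars give the percent of the cells of each library that fell in each class, with 95% exact Clopper-Pearson intervals. Endothelial-like cells reached 76.5% in the GFP-positive library, and fibroblast-like cells reached 54.4% and 53.4% in the GFP-negative and RA libraries.

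The second comparison asked what sets cardiomyocyte-like cells sorted for HCN4-GFP apart from those of the unsorted RA library. Genes of the pacemaker programme were far higher in the GFP-positive library. Shox2 (ENSMUSG00000027833), a homeobox factor needed for the sinus node, was at 439 CPM (417 to 462) against 0 UMIs in RA, at least 150.2-fold higher, and was read in 90.5% of the GFP-positive cardiomyocyte-like cells. The pacemaker channel gene Hcn4 was higher as well, at 7.70 CPM (5.03 to 11.3) against 0 UMIs, at least 2.63-fold. That bound rests on 26 UMIs and leaves out their counting error. Genes of working atrial muscle went both ways, with 6 of 12 lower, among them the natriuretic peptide gene Nppa at 1719 CPM (1675 to 1764) against 13262 CPM (13040 to 13486) and the gap junction gene Gja1 at 28.4 against 188 CPM.

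All 17 measured pacemaker genes were higher in the GFP-positive library, with a median log2 ratio of 3.30, or 2.86 with members at 0 UMIs put at their bound, above all of the random lists (percentile 100). With 5 UMIs added to each sum the median was 2.20. Tbx3, which represses the atrial programme, was at 68.1 against 1.95 CPM, where the RA value rests on 2 UMIs (log2 ratio 4.81, interval 3.26 to 8.18). The calcium channel genes Cacna1g (56.5 against 7.80 CPM), Cacna1d (40.3 against 6.82 CPM) and Cacna2d2 (260.5 against 14.6 CPM, 17.3-fold) were also higher. Vsnl1, Rgs6, Cpne5 and Ntm ran from 2.91-fold (Vsnl1, 270.2 against 92.6 CPM) to 9.15-fold (Ntm, 174 against 18.5 CPM). Smoc2 was at 266 CPM against 3 UMIs in RA. Isl1, Tbx18, Bmp4, Igfbp5 and the gap junction gene Gjc1 were higher too, though each had a higher level in another cell class.

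Thinning every cell to 2000 UMIs left Shox2 in 50% of the GFP-positive cardiomyocyte-like cells, against 0.518% of the endothelial-like cells of that library. Without thinning these shares were 90.5% and 2.83%, at median depths of 19413 and 11424 UMIs. Nppa after thinning was in 14.9% of the GFP-positive and 91.5% of the RA cardiomyocyte-like cells, and in 2.39% and 22.3% of the endothelial-like cells of those libraries. Hcn4 was in 12.5% of the GFP-positive cardiomyocyte-like cells before thinning and in 0.595% after it, against 2.27% and 0.239% of the endothelial-like cells.

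Of 12 measured working atrial genes, 6 were lower, 3 higher and 3 between, with a median log2 ratio of -0.74 (-0.85 to -0.66), below all of the random lists. The lower members also held the conduction gap junction gene Gja5 (68.1 against 192 CPM), the atrial growth factor Bmp10 (8.88 against 82.8 CPM), the calcium pump regulator Sln (3125 against 6786 CPM) and Pam. The higher members included Stard10 (724 against 362 CPM) and the potassium channel gene Kcna5 (9.17 CPM, at least 3.14-fold against 0 UMIs). The atrial myosin light chain gene Myl4 lay between, at 11597 against 16366 CPM.

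Of 11 His bundle genes 6 were higher, 1 was lower and 4 were between, with a median log2 ratio of 0.84 (0.36 to 1.27; percentile 99.9). Cntn2, a cell adhesion gene of the conduction system, was at 27.5 CPM against 0 UMIs (at least 9.42-fold), Id2 at 564 against 239.7 CPM, Kcne1 at 56.2 against 24.4 CPM and Etv1 at 35.5 against 19.5 CPM. Gja5 was the lower member, and Nkx2-5, at 201 against 299 CPM, lay between with Tbx5, Slit2 and Scn10a.

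Among 4 ventricular genes the myosin light chain gene Myl2 was at 576 CPM against 1 UMI in RA, and was read in 44.0% of the GFP-positive cardiomyocyte-like cells. Lbh was higher as well (257 against 48.7 CPM), Myl3 was lower (411 against 755 CPM) and Myh7 lay between, for a median log2 ratio of 0.90 (percentile 99.9). Calcium handling genes were mostly level, with 1 higher (Ryr2, the calcium release channel gene, 334.7 against 129.6 CPM), 10 between and a median log2 ratio of 0.29, which was -0.000793 when only the larger cardiomyocyte-like cluster was used. Oxidative metabolism genes had 1 higher (Ppargc1a), 1 lower (Ckmt2) and 9 between, median -0.29. Cell cycle genes had 7 higher, such as Top2a (52.1 against 6.82 CPM), 3 lower, such as Mcm2 (13.02 against 32.2 CPM), and 6 between, median 0.31.

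Immediate early and heat shock genes moved with the pacemaker genes. Of 11 dissociation stress genes 10 were higher in the GFP-positive library, among them Fos (969.6 against 307 CPM), Fosb (138 against 38.0 CPM) and Dnajb1 (129 against 35.1 CPM), with a median log2 ratio of 1.38 (1.24 to 1.57; percentile 100). All of them but Fosb had a higher level in another class. Extracellular matrix genes, each higher in another class, had 4 higher (Eln, 1188 against 112 CPM), 8 lower (Postn, 38.2 against 405 CPM, and Mfap4, 17.2 against 151 CPM) and 2 between, median -0.84.

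Outside the lists, the signalling gene Bmp2 (175 CPM, at least 59.7-fold) and the chitinase gene Chit1 (143 CPM, at least 48.8-fold) were read at 0 UMIs in RA. Calca, which encodes calcitonin and a vasoactive neuropeptide, was at 154 CPM against 1 UMI (ratio 106, log2 interval 4.82 to 12.61). Rec114, a meiotic recombination gene, was at 211 CPM against 2 UMIs. Chit1 and Calca were among the leading genes of sub-cluster 1 of this class, which held 50 of the 168 GFP-positive cells. The lower genes were the natriuretic peptide gene Nppb (3.85 against 148 CPM, 37.2-fold), the vascular growth factor gene Angpt1 (6.81 against 99.4 CPM), the myoglobin gene Mb (106.5 against 804.9 CPM), Fgf12 (51.2 against 248.5 CPM), Hopx (131 against 570.02 CPM), Lad1 (9.77 against 59.4 CPM) and the transcript RP23-378D16.4. Some of these may have come with RNA or doublets of other classes. Of the 71 RA cells, 28 were in sub-cluster 5 of this class, whose leading genes included Col1a1, Postn and Dcn of fibroblasts beside Angpt1, Bmp10 and Nppb, and 33 were in sub-cluster 6, which was led by haemoglobin genes beside Mb and RP23-378D16.4. These held 3 and 1 of the GFP-positive cells, and in the whole class Hba-a1 was at 20.4 against 6917 CPM, Col1a1 at 64.2 against 196 CPM and Postn at 38.2 against 405 CPM.

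The third comparison set the GFP-positive cardiomyocyte-like cells against those that the same sort left behind. Of the 63 GFP-negative cells 25 each were in sub-clusters 5 and 6, so the limit given above for fibroblast and haemoglobin RNA holds here too, for Angpt1, Bmp10, Mb and the matrix genes in particular. The direction of the pacemaker and atrial genes was as against RA. Shox2 was 59.7-fold higher (439 against 6.79 CPM), and Hcn4 was at least 2.27-fold higher against 0 UMIs. Nppa was 5.61-fold lower (1719 against 9652 CPM), Gja1 was at 28.4 against 139 CPM and Bmp10 at 8.88 against 75.8 CPM.

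Again all 17 pacemaker genes were higher (median log2 ratio 3.41, 2.26 with members at 0 put at their bound, and 1.80 with 5 UMIs added). Working atrial genes had 3 higher, 6 lower and 3 between (median -0.67), and His bundle genes 5 higher, 1 lower and 5 between (median 0.82, percentile 99.9), with Cntn2 at least 8.11-fold higher. Ventricular genes had a median of 0.05, which was 1.69 with only the larger cardiomyocyte-like cluster, and Myl2 lay between at 576 against 690.4 CPM, although 44.0% of the GFP-positive and 14.3% of the GFP-negative cells had a Myl2 UMI. The highest other genes were Rec114 (at least 62.2-fold), Bmp2 (at least 51.4-fold), Chit1 (at least 42.0-fold), the calcium-binding gene Pvalb (688 against 6.79 CPM, 93.5-fold), Calca and the iron hormone gene Hamp (107 CPM against 1 UMI). The lowest were Angpt1 (6.81 against 114 CPM), the skeletal actin gene Acta1 (51.8 against 515 CPM), Mb (106.5 against 1000.5 CPM), Fgf12, Lmod3, Doc2g and Pttg1. Few of the GFP-negative cells had an Acta1 UMI, and its GFP-positive level was not under that of RA, as given below. Among the highest, Pvalb, Chit1 and Calca were leading genes of sub-cluster 1, which held 50 of the 168 GFP-positive cells.

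Calcium handling genes had 2 higher and 9 between (median 0.17), oxidative metabolism genes 1 higher and 10 between (median -0.11) and cell cycle genes 2 higher and 14 between (median 0.03). With only the larger cardiomyocyte-like cluster the first pair of medians were -0.029 and 0.093. Dissociation stress genes had 9 higher and 2 between (median 0.92), and extracellular matrix genes 3 higher, 8 lower and 3 between (median -1.58, and -0.77 with doublets removed by rank of score), with Col1a1 at 64.2 against 589.6 CPM.

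GFP-negative and RA cardiomyocyte-like cells, compared as the background for both, had few called differences in the pacemaker, atrial and His bundle lists. Of 11 measured pacemaker genes 10 lay between and Smoc2 was higher (14.7 CPM against 3 UMIs in RA), with a median log2 ratio of -0.09. Shox2, in 5 of the 63 GFP-negative and 0 of the 71 RA cells, had too few UMIs to be measured. With so few cells, a gene at low level could differ and still lie between. All 11 working atrial genes (median -0.13) and all 7 His bundle genes (median -0.09) lay between, as did 10 calcium handling (median 0.10) and 11 oxidative metabolism genes (median -0.15). Myl2 was at 690.4 CPM in 14.3% of the GFP-negative cells against 1 UMI in RA, and the ventricular median was 0.21, which was -1.06 with only the larger cardiomyocyte-like cluster. Acta1 (515 against 39.0 CPM, in 12.7% and 18.3% of the cells) and Tnnt1 (338 against 93.5 CPM) were higher, and Nppb (30.6 against 148 CPM) and Pgk1 (97.3 against 242 CPM) were lower. Cell cycle genes had 3 higher, 2 lower and 10 between (median 0.49), dissociation stress genes 4 higher, 1 lower and 6 between (median 0.52), and extracellular matrix genes 7 higher and 7 between (median 0.76, and 1.47 with the stricter filter).

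The study's title names His-bundle-like cells, so the GFP-positive cardiomyocyte-like cells were compared among themselves. They fell into 4 sub-clusters of 31, 50, 35 and 36 cells, numbered 0 to 3, that held at most 1 cell of each other library, plus 12 cells in a cycling sub-cluster shared with both other libraries and 4 cells in sub-clusters 5 and 6, which were mostly of the other libraries. Sub-cluster 1 had several of the His bundle genes, with Cntn2 at 76.3 against 10.0 CPM in the other GFP-positive cardiomyocyte-like cells and Etv1 at 83.0 against 18.5 CPM. It also had Shox2 at 742 against 330.4 CPM and Myl2 at 1652 against 190.1 CPM. Sub-cluster 0 had the sinus node genes Tbx18 (97.2 against 17.2 CPM) and Isl1 (35.5 against 3.30 CPM). Sub-cluster 2 had the atrial genes Nppa (5559 against 709.7 CPM) and Gja5 (166 against 42.2 CPM).

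In sub-cluster 1, 7 of 11 His bundle genes were higher and 4 were between, with a median log2 ratio of 1.59 (0.88 to 1.90; percentile 100). Besides Cntn2 and Etv1 the higher members included Nkx2-5 (311 against 162 CPM), Sema3a, Slit2 and Scn10a, while Gja5, Id2, Kcne1 and Tbx5 lay between. With finer sub-clusters, 27 of the same 50 cells had a median of 0.87. Its ventricular median was 1.56 (Myl3 764 against 284 CPM, Lbh 521 against 162 CPM). Of 17 pacemaker genes 7 were higher (Smoc2 504 against 180.5 CPM, Cpne5 334 against 134 CPM), 4 lower (Tbx3 49.4 against 74.8 CPM, Tbx18 2.24 against 43.4 CPM) and 6 between, median 0.57.

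In sub-cluster 0 the His bundle median was -1.79 and the working atrial median -2.02 (Nppa 13.9 against 2124 CPM), with 8 pacemaker genes higher, 3 lower and 6 between (median 0.42). Hcn4 was there at 15.4 against 5.86 CPM and Shox2 was lower, at 231.5 against 488 CPM. Sub-cluster 2 had 13 pacemaker genes lower and 4 between (median -1.49) and a working atrial median of 0.69, with Bmp10 in 5.71% of its cells. Sub-cluster 3 had Shox2 at 605 against 394 CPM and Id2 at 1226 against 387 CPM, with a His bundle median of 0.06. Its dissociation stress median, 0.51, was the highest of the 4 sub-clusters.

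At the level of single cells, 41 of the 168 GFP-positive cardiomyocyte-like cells had UMIs of both Shox2 and Cntn2 (24.4%), and 38 would be met if the genes were independent. After thinning, in a random draw separate from that of the shares above, 4 cells had both. Cntn2 was in 51.0% of the cells of sub-cluster 1 before thinning and in 11.8% after it, against 29.7% of sub-cluster 3, 5.56% of sub-cluster 2 and 3.23% of sub-cluster 0 before thinning, at median depths of 17175, 18784, 19993 and 20285 UMIs. Shox2 and Nppa met in 54 cells against 57 under independence, and after thinning in 5 against 13.2. In that draw Nppa was in 60 of the 71 RA cells, beside the 91.5% of the first draw.

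**Figure D2:**
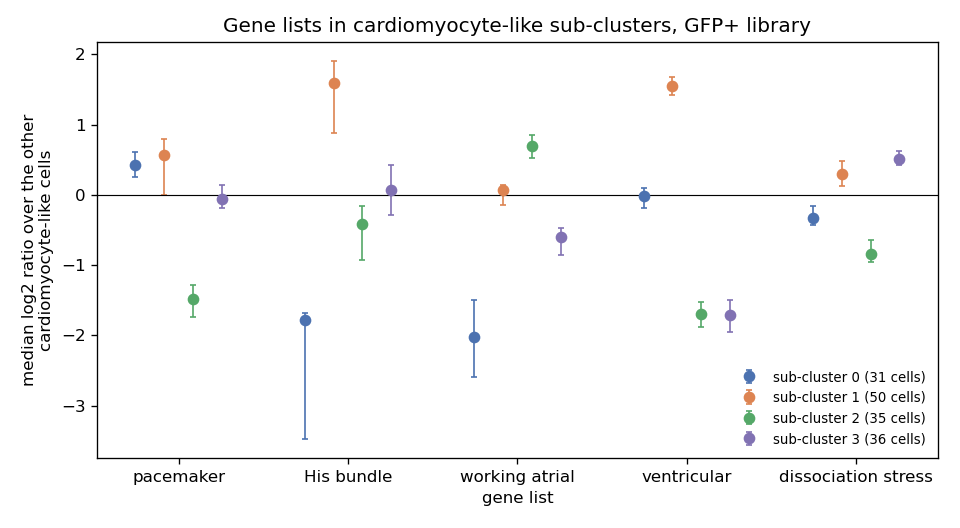
Points give the median log2 ratio of 5 gene lists in each sub-cluster of GFP-positive cardiomyocyte-like cells over the other cells of that class in the library, with 95% counting intervals. The His bundle list was highest in sub-cluster 1 (1.59) and lowest in sub-cluster 0 (-1.79), and the working atrial list was highest in sub-cluster 2 (0.69).

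The fourth comparison, prompted by the endothelial progenitor subtypes in the study's title, set GFP-positive endothelial-like cells against those of the RA library. Most arterial genes were higher in the GFP-positive cells, while matrix genes went both ways. Among the higher single genes, the elastin gene Eln was at 14235 against 339.8 CPM (41.9-fold), Fbln5, which organises elastic fibres, at 1072 against 9.29 CPM (114-fold), and the crosslinking enzyme gene Lox at 136 against 6.29 CPM. The gap junction gene Gja5, an arterial marker, was 26.5-fold higher (83.5 against 2.997 CPM), and the Notch ligand gene Jag1 was at 92.9 against 11.1 CPM. Of 7 capillary genes 3 were lower, among them Gpihbp1, which anchors lipoprotein lipase (161 against 411 CPM).

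The 2 sets of cells came from different clusters. Most GFP-positive endothelial-like cells were in 8 clusters that held few cells of the other libraries, and most RA and GFP-negative ones were in clusters 11 and 14. A type of cell that forms clusters in 1 library alone cannot be separated from that library.

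Arterial genes had 6 higher, 1 lower (Dll4, 17.6 against 27.3 CPM) and 2 between, with a median log2 ratio of 1.24 (1.01 to 1.49; percentile 100), and Gja4 was at 326.5 against 107.6 CPM. Capillary genes had 1 higher (the water channel gene Aqp1, 550.2 against 143 CPM), 3 lower and 3 between (median -0.76, and -0.17 with classes from each cell's own marker UMIs). Venous genes had 1 higher (Vwf, 554 against 58.1 CPM), 1 lower (Aplnr, 123 against 209.5 CPM) and 3 between (median 0.14, percentile 80.9). The endothelial progenitor list split, with Procr (361 against 72.2 CPM), Lmo2 (352 against 135.5 CPM) and Prom1 (15.8 against 8.09 CPM) higher, Kit (12.7 against 38.4 CPM) and Cxcr4 lower, and Cd34, Kdr, Tek, Tal1 and Sox17 between. Its median was 0.08 (-0.09 to 0.21; percentile 71.9).

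Other genes higher in the GFP-positive endothelial-like cells included Ccl21a (ENSMUSG00000094686), a lymphatic chemokine (1969 CPM against 0 UMIs, at least 2190.5-fold). Ccl21a was the leading gene of endothelial sub-cluster 2, which held 206 GFP-positive cells and 0 RA cells. The hedgehog ligand gene Dhh (119 against 2.70 CPM, 41.8-fold), Inhba (68.8 against 1.20 CPM), Serpina1b (133 CPM against 1 UMI) and Gkn3 (122 CPM against 2 UMIs) were higher too. Lower were Ggt5 (8.46 against 57.5 CPM), Cd300lg (21.0 against 100.7 CPM), Tgfbi (79.0 against 342 CPM), the imprinted gene Mest (564 against 2425 CPM), Arhgap18 and Pcdh17. Extracellular matrix genes had 6 higher, 5 lower and 3 between (median 0.25), where Mfap4 and Postn among the lower ones are higher in fibroblast-like cells. Dissociation stress genes had 9 higher and 2 between (median 0.92), with Fos at 1493 against 591 CPM and Atf3 at 285 against 69.8 CPM. Cell cycle genes had 5 lower (Mcm3, 20.6 against 37.8 CPM) and 11 between, median -0.48.

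Against the GFP-negative library the same endothelial groups were set beside each other. Arterial genes again had 6 higher, 1 lower and 2 between (median 1.05), with Gja5 at 83.5 against 3.09 CPM. Capillary genes had 6 lower, such as the fatty acid binding gene Fabp4 (2566 against 5992 CPM) and Gpihbp1 (161 against 633 CPM), and Aqp1 higher (median -1.23). Endothelial progenitor genes had 3 higher, 2 lower and 5 between (median 0.05), with the same members as against RA, and venous genes a median of 0.49 with Vwf at 554 against 37.5 CPM. Extracellular matrix genes had 5 higher, 5 lower and 4 between (median -0.32).

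The stress median was 0.92 (8 higher, 3 between) and the cell cycle median -0.38 (2 higher, 3 lower, 11 between). Gkn3 (at least 92.3-fold) and the Wnt amplifier gene Rspo3 (73.7 CPM, at least 55.6-fold) were read at 0 UMIs in the GFP-negative cells, and the basal integrin gene Itgb4 (52.1 against 1.76 CPM) and Pthlh (51.6 against 1.76 CPM) were higher. Cd300lg (21.0 against 101.04 CPM), Sparcl1 (193 against 694 CPM) and C1qtnf9 (12.4 against 56.0 CPM) were lower.

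Between GFP-negative and RA endothelial-like cells all 10 progenitor genes lay between (median 0.01). Capillary genes had 4 higher and 3 between (median 0.62), with Cd36 at 360 against 211 CPM. Arterial genes had 2 higher and 7 between (median 0.18), venous genes 1 lower and 4 between (median -0.24), dissociation stress genes 3 higher, 2 lower and 6 between (median 0.13), cell cycle genes 3 lower and 13 between (median -0.13), and extracellular matrix genes 8 higher and 6 between (median 0.65). Eln was at 1130.0 against 339.8 CPM and Fbln5 at 60.9 against 9.29 CPM. Eln also differed in classes not known for making it, at 632 against 62.2 CPM in macrophage-like and 531 against 37.5 CPM in erythroid-like cells, so free RNA may carry the matrix difference.

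Within the GFP-positive library the endothelial progenitor list was highest in endothelial sub-cluster 10, which held 128 of its cells. There 5 of 10 members were higher, 2 lower and 3 between, with a median log2 ratio of 0.63 (0.55 to 0.70) over the other endothelial-like cells of that library. Sox17, a factor of arterial endothelium, was at 607 against 49.1 CPM, the chemokine receptor gene Cxcr4 at 50.9 against 1.02 CPM, Prom1 at 49.9 against 13.5 CPM, Lmo2 at 646 against 332 CPM and Kdr at 234 against 138 CPM, while Kit and Procr were lower. Arterial genes were also highest there (8 higher, 1 between). Cd34 was instead highest in sub-cluster 0 (1021 against 383 CPM) and sub-cluster 12 (1004 against 399 CPM). Procr was higher in sub-clusters 5 (671 against 315 CPM) and 8 (652 against 343 CPM), which also had venous medians of 0.87 and 1.01. Kit was higher in sub-cluster 1 (37.9 against 6.82 CPM), which had the lowest progenitor median (-0.78) and the endocardial gene Npr3. Sub-cluster 11 had all 7 capillary genes higher (median 3.11) and 15 of 16 cell cycle genes.

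Fibroblast-like, macrophage-like and erythroid-like cells had enough cells only in the GFP-negative and RA libraries, where the comparison asked how the cells outside the reporter gate differed from those of RA. In fibroblast-like cells the opioid precursor gene Penk was at 78.7 against 0.450 CPM (159-fold), Ly6a at 107 against 1.71 CPM, the neuropeptide gene Npy at 115 against 2.16 CPM, the neurotrophin receptor gene Ntrk2 at 52.7 against 1.08 CPM, and Agtr2, Gdf10 (151 against 13.2 CPM) and Clec3b (293 against 44.0 CPM) were higher. Tcf21, a factor of epicardium-derived cardiac fibroblasts, was lower at 214 against 776 CPM, with Moxd1 (20.1 against 92.1 CPM), Smad6 (41.2 against 109 CPM) and Spry2 (49.1 against 119 CPM). Clusters 23 and 24 held 350 and 416 of the 1645 GFP-negative cells, and clusters 28 and 29 held 290 and 173 of the 685 RA cells. Penk, Ly6a, Ntrk2, Agtr2, Gdf10 and Clec3b were all leading genes of cluster 23, which held only 1 RA cell. Their differences thus go with a cluster nearly absent from RA. Cluster 28 had Rgs5 and Tagln, markers of the smooth muscle or pericyte set, among its leading genes.

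Extracellular matrix genes in fibroblast-like cells had 2 higher (Lox, 195.5 against 83.1 CPM, and Eln), 1 lower (Postn, 3438 against 5672 CPM) and 11 between, with a median log2 ratio of 0.36 (0.31 to 0.40), which was 0.21 with finer clusters. Dissociation stress genes had 4 higher, among them Egr1 (749 against 481 CPM), and 7 between (median 0.48, from 0.16 to 0.60 under other settings). Cell cycle genes had Mki67 (24.3 against 13.6 CPM) and Cenpf higher and 14 between, with a median of -0.17 that was 0.15 with list genes allowed among the variable genes.

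In macrophage-like cells the anti-inflammatory cytokine gene Il10 (97.6 against 11.6 CPM), F13a1 (325.5 against 106 CPM) and the mannose receptor gene Mrc1 (297 against 100.3 CPM) were higher in the GFP-negative library. Spp1 (105 against 732 CPM), Mmp12 (21.3 against 102 CPM), the class II antigen gene H2-Eb1 (134 against 461 CPM) and Cd207 (145 against 392 CPM) were lower. Haemoglobin RNA differed too, with Hba-a1 at 5769 against 47111 CPM in these cells. Stress genes had 4 higher and 7 between (median 0.36) and cell cycle genes 3 lower and 13 between (median -0.21). Erythroid-like cells had Gpx1 (1398 against 891.5 CPM) and Cdc25b (54.5 against 27.8 CPM) higher and the carbonic anhydrase gene Car2 (92.9 against 199.6 CPM) lower. Their stress genes had 7 higher, each at a higher level in other classes, and 4 between (median 0.79, and 0.089 with classes from own marker UMIs), and their cell cycle genes 1 higher, 4 lower and 4 between (median -1.24). The 4 lower ones each had a higher level in other classes. The higher one, Ube2c (84.9 against 51.0 CPM), was not under 0.5 times the level of another class. Pooled over the libraries it stood at 70.8 CPM, against 124 CPM in the highest other class.

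The last comparison asked which classes carried the reporter that defined the sort. The GFP feature had 2191 UMIs (43.5 CPM) in the GFP-positive library, 19 in the GFP-negative and 14 in the RA library. In the GFP-positive library it was highest in cardiomyocyte-like cells, at 128 CPM (116 to 140) and in 66.7% of the cells. Endothelial-like cells had 43.9 CPM (41.8 to 46.1; 37.9% of cells) and epicardial-like cells 16.9 CPM (14.4 to 19.8; 24.6% of cells). After thinning these shares were 19.0%, 7.53% and 2.71%. Endothelial-like cells of the other libraries had 3.53 CPM (GFP-negative, 8 UMIs) and 0.899 CPM (RA, 3 UMIs). The 27 macrophage-like cells of the GFP-positive library, which are not known to make HCN4, were at 42.3 CPM (23.7 to 69.7; 15 UMIs).

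Hcn4 itself was read at far lower levels, with 7.70 CPM in the cardiomyocyte-like cells (12.5% of cells), 1.80 CPM in the endothelial-like cells (2.27% of cells) and 0.869 CPM in the epicardial-like cells (1.55% of cells). In that library 1 of the 27 macrophage-like cells (3.70%, 2.82 CPM) and 2 of the 37 unnamed cells (5.41%, 1.82 CPM) also had Hcn4 UMIs, 1 and 2 in all, too few to set a background level. The whole GFP-positive library had 102 Hcn4 UMIs, the GFP-negative library 4 and the RA library 0. Among the cardiomyocyte-like sub-clusters, GFP after thinning was in 38.7% of sub-cluster 0 and 33.3% of sub-cluster 1, and in 8.33% of sub-cluster 2 and 2.70% of sub-cluster 3, the last resting on 1 cell. Before thinning these shares were 90.3%, 86.3%, 27.8% and 59.5%, so the order of the last pair was the other way round.

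**Figure D3:**
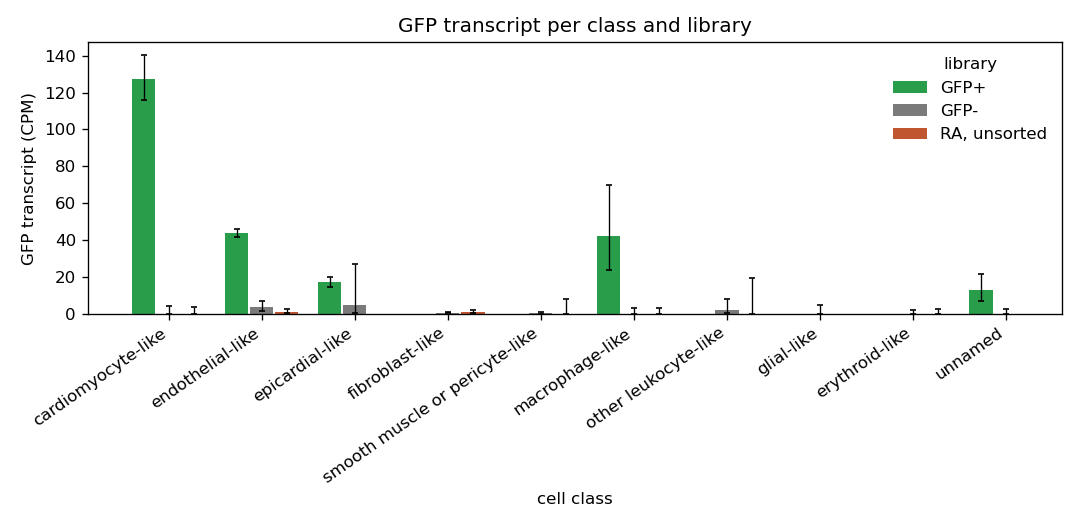
Bars give GFP transcript CPM per class and library for classes with at least 20 cells, with 95% exact Poisson intervals. In the GFP-positive library the cardiomyocyte-like, endothelial-like and epicardial-like cells stood at 128, 43.9 and 16.9 CPM.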

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

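Of the tests in this part, the one of doublets with cardiomyocyte-like cells and the one of different kinds of cell were chosen before their results were seen, and the other tests were chosen only after the result was seen.

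GFP transcript was read in endothelial-like (43.9 CPM) and epicardial-like (16.9 CPM) cells of the GFP-positive library, where activity of the reporter in these cells, which the sort selects for, stays open as the biological explanation. Against free RNA from cardiomyocyte-like cells, GFP in endothelial-like cells stood at 34.4% (30.9% to 38.4%) of its cardiomyocyte-like level while cardiomyocyte markers stood at 0.375% to 1.51%, and against doublets with cardiomyocyte-like cells, those markers were 1.01 times (0.929 to 1.09) as high in endothelial-like cells with a GFP UMI as in those without, at 496.8 and 492.6 CPM. In epicardial-like cells free RNA from all cells of the library cannot be told apart from expression, since GFP stood at 38.8% (32.8% to 45.7%) of its level over all cells and the highest cardiomyocyte marker, Tnni1, at 33.2% with an upper limit of 36.7%. That test was tried in 3 forms that disagreed, because GFP in epicardial-like cells stood at 38.6% (32.5% to 45.5%) of its endothelial-like level, within the span of endothelial markers from Flt1 (5.93%) to Kdr (55.1%) but above the lowest of them, and the form of the test on cardiomyocyte-like cells was also reworded with the same outcome. Macrophage-like cells stood at 96.8% (54.1% to 160.03%) and unnamed cells at 29.2% (15.9% to 49.0%) of the level over all cells, so free GFP RNA may make up a share of the GFP in every class of this library.

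Some His bundle and some pacemaker genes were high together in cardiomyocyte-like sub-cluster 1, with Cntn2 at 76.3 CPM and Shox2 at 742 CPM. Other pacemaker genes, Tbx3 and Tbx18 among them, were lower there. A conduction cell of mixed programme stays open as the biological explanation. Against dissociation stress as a sufficient cause, sub-cluster 3 had the highest stress list and a His bundle list at percentile 25.5 among random lists. That test did not look at stress within sub-cluster 1, so a part played by stress there stays open. Doublets of 2 other kinds of cell cannot be told apart from 1 kind of cell, since only 2 of the 7 higher His bundle genes, Cntn2 (at most 26.9 CPM elsewhere) among them, stood above every other class and sub-cluster, while Etv1 (86.6 CPM in cluster 17), Slit2 (102 CPM in cluster 29), Sema3a (104 CPM in endothelial sub-cluster 7) and Nkx2-5 (355 CPM in sub-cluster 6) were higher elsewhere and Scn10a (8.95 CPM in sub-cluster 5) overlapped. The doublet caller has not worked, and after removal of doublets by rank of score the sub-cluster's His bundle median was 1.45.

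Dissociation stress genes were higher in the GFP-positive library than in RA, with medians of 1.38 in cardiomyocyte-like and 0.92 in endothelial-like cells. Handling shared by both sorted libraries was argued against as the whole cause by endothelial-like cells, where the GFP-positive library stood above the GFP-negative one by a median of 0.92, as in cardiomyocyte-like cells (0.92), but it stays open for a part, since the GFP-negative library itself stood above RA by 0.52 in cardiomyocyte-like, 0.48 in fibroblast-like and 0.13 in endothelial-like cells, at percentiles of 99.99, 100 and 99.6. Different kinds of cell in the libraries were argued against only within the sub-clusters that the GFP-positive and RA libraries shared. Their medians were 1.60 (cardiomyocyte-like 4), 1.27 (endothelial-like 9) and 0.90 (endothelial-like 11), each above the random lists. They held 12, 137 and 62 GFP-positive cells but only 9, 8 and 11 RA cells, and variation between cells was not measured. Handling of the GFP-positive library alone cannot be told apart from the group, because that group had 1 library, and free RNA stays open in cardiomyocyte-like cells, where all higher members but Fosb had a higher level in another class. No biological explanation was tested.

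Some items stood out because no comparison took them in. The reporter feature hcn4-h2bG-3 had 7 UMIs in the GFP-positive library and 0 in the others. Cluster 10 held 28 cells of the GFP-positive library and none of the others, with the airway secretory genes Scgb3a2 (137006 CPM), Scgb3a1 (115388 CPM) and Scgb1a1 (35530 CPM). Cluster 17 held 18 cells of the GFP-negative library and 9 of the GFP-positive one, with Ccl11 (1719 CPM), Thbs4 (769 CPM) and Col2a1 (896 CPM). Cluster 30 held 123 cells of the GFP-negative library and 2 of the others, with the cartilage genes Col2a1 (1413 CPM), Mia (526 CPM) and Col9a1 (475 CPM). Only 20%, 46.4% and 21.6% of its cells had a UMI of these genes, against 88.8% for Dlk1 (3557 CPM). The cartilage genes therefore do not describe most of its cells.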

How the results depend on the processing

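Tests named here as added were chosen only after the result was seen. No paired analysis was possible because each group had 1 library. A value under another setting counts as the same where it lies inside the 95% counting interval of the reported value. It counts as reversed only where that interval leaves out equality and the sign changes, so a change of sign from a value whose interval holds equality is not a reversal. The rest count as moved. Over 64 results, 738 values under other settings left 661 the same, moved 72 and reversed 5. Of these, 151 values for 17 results were planned before the data were examined, and 139 were the same, 12 had moved and 0 were reversed. The 587 added values gave 522 the same, 60 moved and 5 reversed. The cause of a move was not tested unless its sentence gives it.

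The cardiomyocyte-like share of the GFP-positive library was 3.93% with classes taken from each cell's own marker UMIs. With only the larger cardiomyocyte-like cluster the shares were 1.29% in the GFP-negative and 2.96% in the RA library, by construction of that setting. The pacemaker medians were 2.20 over RA and 1.80 over GFP-negative with 5 UMIs added to each sum, which pulls genes near 0 UMIs toward equality, and all 17 members stayed higher. The pacemaker median of GFP-negative over RA ran from -0.11 to 0.15. The bound for Hcn4 ran from 1.89-fold to 2.76-fold over RA and from 1.83-fold to 2.36-fold over GFP-negative.

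The extracellular matrix median of fibroblast-like cells, 0.36, moved in 7 of 12 settings. It was 0.23 with no filter, 0.26 with the stricter filter, 0.22 with doublets kept, 0.21 at resolution 2, 0.30 with list genes allowed among the variable genes, 0.29 with classes from own marker UMIs and 0.48 with median-of-ratios scaling. That scaling moved the median of all fibroblast genes by 0.12, and in erythroid-like cells the scalings moved it by -0.18 and -0.23. Elsewhere the move was under 0.1. In the same cells the dissociation stress median, 0.48, moved in 8 of 12 settings (0.16 to 0.60), and the cell cycle median, -0.17, reached -0.59. The stress median of erythroid-like cells, 0.79, moved in 5 of 11 settings, down to 0.089.

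The endothelial progenitor median of GFP-negative over RA ran from -0.01 to 0.08 under 12 settings. The His bundle median of sub-cluster 1, 1.59, was 0.87 at sub-cluster resolution 2, where the group held 27 of the same 50 cells.

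The reversed values were these. With only the larger cardiomyocyte-like cluster, calcium handling was -0.000793 over RA and -0.029 over GFP-negative, and oxidative metabolism was 0.093 over GFP-negative. The extracellular matrix median of endothelial-like cells over GFP-negative was 2.997 over the 4 members left without those higher in other classes. That setting compares levels pooled over the libraries, where 2511 of the endothelial-like cells were GFP-positive, so it keeps members that are high in that library and its values test nothing in this class. The cell cycle median of fibroblast-like cells was 0.15 with list genes allowed among the variable genes. The cause was not tested for the others, and with the settings of the report none of those lists had a median past 0.58 in either direction. The ventricular median of GFP-negative over RA was 0.21 and became -1.06 with only the larger cardiomyocyte-like cluster, and that of GFP-positive over GFP-negative went from 0.05 to 1.69. In cardiomyocyte-like cells the extracellular matrix median went from -0.84 to -0.38 over RA with the stricter filter, from -1.58 to -0.77 over GFP-negative without doublets by rank of score, and from 0.76 to 1.47 for GFP-negative over RA with the stricter filter. The His bundle median over GFP-negative went from 0.82 to 0.39 with 5 UMIs added. With classes from own marker UMIs the endothelial-like medians over RA were 0.91 for arterial genes, -0.17 for capillary genes and 0.092 for extracellular matrix genes.

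A further 601 values of 54 list results, in classes the lists were not made for, had 542 the same, 52 moved and 7 reversed, 5 of these with 5 UMIs added, and they were set aside after the reversals were seen. Hcn4 with 5 UMIs added was not run, since it has no meaning for a bound, nor was Hcn4 of GFP-negative over RA, with 0 UMIs in both. Cell cycle genes of erythroid-like cells gave no value with the stricter filter.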

Other observations

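The tests behind this part were chosen only after the result was seen, and they rest on sub-clusters whose leading genes also defined them. Endothelial-like cells of the GFP-positive library included a lymphatic group, sub-cluster 2, with 206 GFP-positive and 3 GFP-negative cells and the lymphatic genes Ccl21a and Mmrn1. They also included an endocardial group, sub-cluster 1, with 510 GFP-positive cells, Npr3 at 522 CPM and Tmem108 at 537 CPM. Sub-cluster 14, with 142 RA, 80 GFP-negative and 1 GFP-positive cell, had Npr3 at 523 CPM and Tmem108 at 408 CPM. Kit was at 37.7 CPM in sub-cluster 1, 41.0 CPM in sub-cluster 14 and 43.5 CPM in the capillary sub-cluster 13, so the lower Kit level of GFP-positive endothelial-like cells went with the mix of groups.

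GFP was read in varying shares of the cells of the sub-clusters, over a narrow range in the endothelial-like ones after thinning. After thinning it was in 2.70% to 38.7% of the cells of the cardiomyocyte-like sub-clusters 0 to 4 and in 5.12% to 11.5% of the endothelial-like sub-clusters 0 to 12, and before thinning in 25% to 90.3% and in 26.9% to 67.8%. These shares were taken over the cells of all libraries, and cardiomyocyte-like sub-cluster 4 held 12 GFP-positive cells of 32. The difference between the classes was not tested, nor were differences among the endothelial-like sub-clusters. Before thinning the median depths of these sub-clusters ran from 9259 to 19856 UMIs, so their shares are not at equal depth.

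Bcas3 was lower in the GFP-negative than in the RA library in all 5 classes compared, with 21.5 against 50.7 CPM in cardiomyocyte-like, 15.9 against 62.3 CPM in endothelial-like, 16.8 against 60.0 CPM in fibroblast-like, 20.4 against 59.7 CPM in macrophage-like and 10.3 against 56.3 CPM in erythroid-like cells. A difference shared by all classes belongs to the library and not to a class. Haemoglobin RNA was far lower in the GFP-positive library, with Hba-a1 at 19.4 CPM in its endothelial-like cells against 3242 CPM in those of GFP-negative and 1697 CPM in those of RA. Between GFP-negative and RA the direction differed by class, and in cardiomyocyte-like cells Hba-a1 was at 2513 against 6917 CPM and in macrophage-like cells at 5769 against 47111 CPM. Eln was at 1188 CPM in cardiomyocyte-like and 1153 CPM in macrophage-like cells of the GFP-positive library, close to each other and far under its endothelial-like level of 14235 CPM.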
